A study of Arabidopsis thaliana with 12 samples.

How the data were processed

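RNA was sequenced from whole rosettes of Arabidopsis thaliana grown in short days, in the wild type Col-0 and in the vil1-1 mutant, each kept at 22 °C or at 12 °C. The 12 libraries form 4 groups of 3. The labels number the libraries of each group but do not say whether each came from separate plants, so the p-values measure only the spread between these samples.

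The deposited files give whole-number counts per library and per annotation feature, with no normalization. Per the file headers and rows, the features are Araport11 gene models on the TAIR10 assembly. FastQC, HISAT2, Bowtie2, SAMtools, bedtools and edgeR are named by the authors without version, and the settings of each are not given in the sources used here. Of 1287 pairs in which a gene with at least 100 counts lies wholly inside a gene on the other strand, the inner gene held no more counts than the outer in every library in 1285, as when reads are counted without regard to strand. A gene that lies under another gene would then carry the reads of both, and 2949 genes have at least 50% of their span under a gene on the other strand. Reads shared by close paralogs may be assigned to either copy, which concerns CBF1 to CBF3, KIN1 and KIN2, COR15A and COR15B, and the LHCB1 and RBCS copies.

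The 32833 gene rows were used, and no library was left out. Of these, 32548 matched a locus of a reference annotation. Symbols came from the gene lists below, this annotation or the names in the deposited files, and 14018 rows had one. Totals over the gene rows ranged from 40790180 to 47691710 counts per library. Genes with enough counts by edgeR's filterByExpr were kept, which left 22504 genes tested and took out 10329. At this depth, floors and intervals cover counting error only. A fold against a group with 0 counts was computed against a floor of 3 counts over the group and is a lower bound. With 1 to 3 counts over the group, the ratio is given with its 95% counting interval.

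Counts were scaled with TMM factors and fitted with edgeR 4.0.16 in R 4.3.3, in 1 quasi-likelihood model of the 4 groups with robust dispersion and 8 residual degrees of freedom. The quasi-likelihood F test of edgeR gave a two-sided p per gene, adjusted by Benjamini-Hochberg over all genes tested, and a gene was called at adjusted p under 0.05. The comparisons were 12 °C minus 22 °C within each genotype, vil1-1 minus Col-0 at each temperature, and the difference between the cold responses of the genotypes (the interaction). Levels are CPM, counts scaled by TMM library size, with the SD over 3 libraries. The CPM of VIL1 exons are scaled by the total over the gene rows instead, without TMM factors. Fold changes come from the fit. SE is the size of the log2 fold change divided by the square root of its F statistic, an approximate standard error. It may be too small where a group holds few counts, as for PI4KG3 in Col-0. On simulated data with the same group sizes, from 62.1% to 72.3% of 2-fold changes were found in the single comparisons and 56.7% in the interaction. For 1.5-fold changes these were 34.8% to 43.9% and 18.2%. Of the genes called, 2.2% to 7.1% were unchanged ones. The simulation changed few genes and held no library that stands apart, so recovery in the real data may differ.

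Genes to be named were chosen by a rule fixed before the data were examined. It takes VIL1, CBF1, CBF2 and CBF3, then in each comparison up to 6 rises and 6 falls among nuclear protein-coding genes with a symbol, a fold of at least 2, at least 5 CPM in the higher group and no overlap between libraries. It also takes up to 4 members of each gene list with at least 3 called members or past its test. The other genes named in the text were chosen after their values were seen.

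The 25 gene lists were fixed at the same time. They are CBF and CBF-like factors, CBF upstream regulators, cold-regulated (COR) genes, gibberellin metabolism, DELLA proteins and gibberellin receptors, cell wall expansion, PIF and auxin growth genes, brassinosteroid metabolism, cell cycle and DNA replication, cell cycle inhibitors, the Polycomb and VIN3 family, flowering repressors, flowering promoters, floral and meristem identity genes, seed and embryo markers, root markers, circadian clock, flavonoid and anthocyanin synthesis, nuclear photosynthesis genes, sugar, starch and proline, abscisic acid response, salicylic acid defence, jasmonate, heat shock, and senescence and dark-induced genes. Each was tested with camera (limma 3.58.1) on voom values with a preset correlation of 0.01, adjusted over the 25 lists of a comparison, and again with a correlation estimated per list. Camera compares a list with all other genes.

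Alternatives fixed in advance were RLE size factors, DESeq2 1.42.0, no low-count filter, a filter at 10 CPM in 3 libraries, only the groups compared, the replicate number as a block, nuclear genes only, protein-coding genes only, exon counts, a test against a fold of 1.5, adjusted p under 0.01, no robust dispersion, the fry test for lists, and leaving out each library. Leaving out both Col-0 22 °C libraries with the most chloroplast reads, and the chloroplast share as a covariate, were chosen after seeing the data. In the first of these the lone Col-0 22 °C library is assumed to vary like the other groups. Gene families by symbol were also chosen after seeing the data. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.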

Results

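The data are gene counts from 12 RNA-seq libraries of whole rosettes, 3 from each combination of 2 genotypes and 2 growth temperatures. Col-0 is the wild type, and vil1-1 is a mutant of VIL1, a PHD-finger protein of the VIN3 family that acts with Polycomb repressive complex 2. Plants stayed at 22 °C or at 12 °C, a cool but not freezing temperature, in short days. The comparisons ask how the transcriptome differs between these temperatures, how it differs between the genotypes, and whether the mutant's response to 12 °C differs from that of the wild type, with the CBF genes as a centre of interest. Library totals over genes ran from 40790180 to 47691710 counts. Temperature separated the libraries on the first principal component, which held 50.8% of the variance, and vil1-1 12 °C replicate 1 stood at -61 on the second, which held 10.6%. Chloroplast genes took 2.29% and 3.31% of the counts of Col-0 22 °C replicates 1 and 2, and from 0.13% to 1.2% in the other 10 libraries. The ratio of 5′ UTR to 3′ UTR counts was 0.97, 0.982 and 0.981 in the vil1-1 12 °C libraries, against 0.823, 0.821 and 0.894 in Col-0 12 °C. It was 0.963, 1.013 and 0.811 in Col-0 22 °C and 0.83, 0.858 and 0.846 in vil1-1 22 °C.

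VIL1 (AT3G24440, chromosome 3, 8875784 to 8878481 in TAIR10) lost its last exon in the mutant libraries. This exon (8875784 to 8877297) held 275, 333 and 365 counts in the Col-0 22 °C libraries and 544, 432 and 526 in Col-0 12 °C. It held 0 counts in each of the 3 vil1-1 22 °C libraries, which allows up to 3 counts over the group, and 6, 8 and 6 in vil1-1 12 °C. The first exon (8877747 to 8878481) stood at 4.48 ± 0.76 CPM (SD, n = 3) in vil1-1 and 3.98 ± 1.15 in Col-0 at 22 °C, and at 3.81 ± 0.49 and 5.58 ± 0.44 at 12 °C. The middle exon (8877375 to 8877667) stood at 1.47 ± 0.4 CPM in vil1-1 and 2.31 ± 0.31 in Col-0 at 22 °C, and at 1.1 ± 0.14 and 3.52 ± 0.13 at 12 °C. Over the whole gene, VIL1 stood at 11.9 ± 2.59 CPM in Col-0 and 4.86 ± 0.595 in vil1-1 at 22 °C, 2.45-fold lower in the mutant (log2 -1.29, SE 0.15, adjusted p = 0.000618). At 12 °C it stood at 17.8 ± 0.541 and 4.54 ± 0.297 CPM, 3.92-fold lower (log2 -1.97, SE 0.15, adjusted p = 1.81e-05). VIL1 was higher in each of the 6 Col-0 libraries, from 8.96 CPM, than in any vil1-1 library, at most 5.41 CPM. Within Col-0 it rose 1.49-fold at 12 °C (log2 0.58, SE 0.15, adjusted p = 0.00545), a call that ended without both chloroplast-rich libraries (0.0815), and within vil1-1 it did not pass (log2 -0.10, SE 0.15, adjusted p = 0.644).

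**Figure D1:**
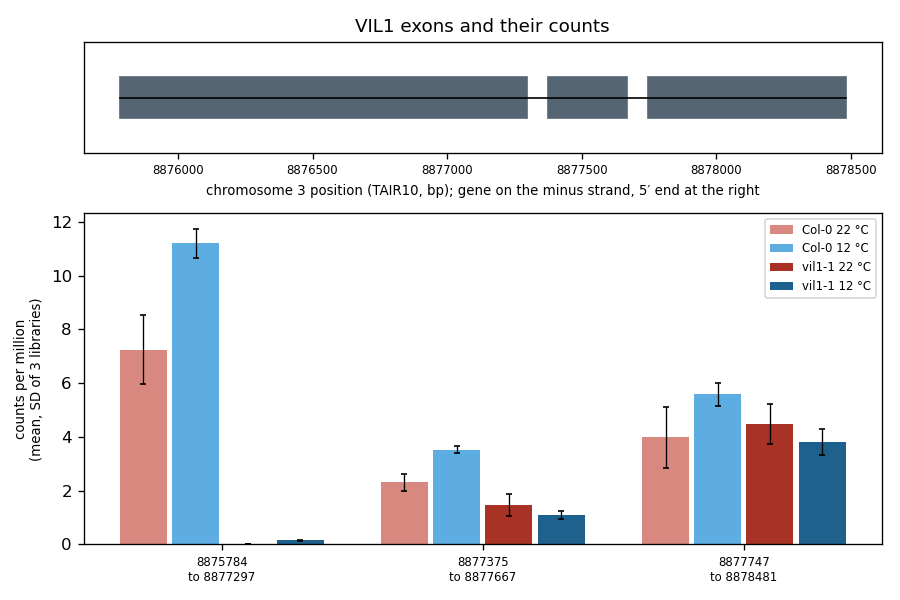
The 3 exons of VIL1 to scale on chromosome 3 (TAIR10, top) and the CPM of each exon by group, without TMM factors (bottom). Bars are means and error bars SD of 3 libraries. The exon from 8875784 to 8877297 stands at 0 and 0.15 CPM in vil1-1 at 22 °C and 12 °C, against 7.25 and 11.2 in Col-0.

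In Col-0, rosettes at 12 °C held far more transcript of the early light-induced proteins, which bind chlorophyll under light stress, than rosettes at 22 °C. ELIP2 was 119-fold higher (log2 6.90, SE 0.28, n = 3, adjusted p = 4.35e-08) and ELIP1 16.4-fold (log2 4.04, SE 0.18, adjusted p = 1.6e-08). GolS3, a galactinol synthase of raffinose synthesis, rose 10.1-fold (log2 3.33, SE 0.20), and PDC1, a pyruvate decarboxylase, rose 9.68-fold (log2 3.27, SE 0.58). VIN3, the Polycomb-associated protein that cold induces, rose 12.5-fold (log2 3.65, SE 0.34, adjusted p = 2.66e-06). Among the falls were genes of jasmonate action, such as VSP1, a vegetative storage protein (log2 -8.64, SE 0.55), and TAT3, a tyrosine aminotransferase (log2 -8.81, SE 0.63), with BAM5, a beta-amylase (log2 -9.15, SE 0.64), and NATA1, an N-acetyltransferase (log2 -9.53, SE 0.62). CYP94B3, which oxidises jasmonoyl-isoleucine, had 0 counts at 12 °C, at least 713-fold lower, and RAP2.6, an ERF transcription factor, was 1020-fold lower with a counting interval from 183 to 40500. The libraries of CYP94B3 and RAP2.6 at 22 °C were uneven, at 17 ± 21.2 and 8.14 ± 10.4 CPM. TCP1 and ASY1 also passed as rises, at 10.2 ± 13.5 and 9.49 ± 13.5 CPM at 12 °C, where the SD exceeds the mean. Without both chloroplast-rich Col-0 22 °C libraries the calls of TCP1 (0.21), ASY1 (0.289) and RAP2.6 (0.15) ended. ASY1 lost its call without any 1 of Col-0 22 °C replicates 1, 2 and 3 (adjusted p = 0.0871, 0.0797 and 0.0625) or Col-0 12 °C replicate 1 (0.0581), and RAP2.6 without any 1 of Col-0 12 °C replicates 1, 2 and 3 (0.0926, 0.089 and 0.131).

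The edgeR quasi-likelihood test called 9483 of 22504 genes in Col-0, 4443 higher and 5040 lower at 12 °C. At a fold of 2 or more, 729 were higher and 1872 lower. Without both Col-0 22 °C libraries with the most chloroplast reads, a choice made after seeing the data, 6272 genes were called. Tested against a fold of 1.5, 2367 genes were called and 28.4% of them were higher, compared with 46.9% in the test against no change.

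Of the CBF transcription factors, which switch on cold-regulated genes and lie side by side on chromosome 4 (13015250 to 13022996, TAIR10), CBF1 (AT4G25490) and CBF3 (AT4G25480) rose in Col-0 at 12 °C. CBF1 went from 1.38 ± 0.599 to 4.14 ± 0.513 CPM (log2 1.59, SE 0.28, adjusted p = 0.000367) and CBF3 from 16.6 ± 2.85 to 28.6 ± 3.79 CPM (log2 0.78, SE 0.14, adjusted p = 0.000778). CBF2 (AT4G25470) stood at 3.7 ± 0.923 and 4.23 ± 0.389 CPM (log2 0.20, SE 0.20, adjusted p = 0.465), and its sign turned (log2 -0.12) without both chloroplast-rich libraries. Reads shared between these similar genes may be assigned to either. The list of CBF and CBF-like factors had 2 of 4 tested members higher (2 when adjusted over the list alone) and camera adjusted p = 0.159. Of 16 CBF upstream regulators, 5 rose and 8 fell (5 and 8 adjusted over the list alone, camera adjusted p = 0.492), among them SCRM2, a homolog of the CBF activator ICE1 (log2 0.59), and the falls PIF3 (-1.28) and ZAT12 (-2.72). Of 19 COR genes, 7 rose and 4 fell (8 and 4 adjusted over the list alone, camera adjusted p = 0.0943). COR15B, a chloroplast-protecting protein, rose (log2 1.05, SE 0.12), as did COR28 (1.77, SE 0.27), while LEA14 fell (-0.75, SE 0.13).

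Jasmonate genes fell in Col-0 at 12 °C, 15 of 16 (15 adjusted over the list alone), with a median log2 of -3.16. The falls covered synthesis enzymes, LOX2 (log2 -3.45, SE 0.16), AOC2 (-2.58, SE 0.14) and AOS (-2.28, SE 0.16), and the repressor JAZ9 (-4.51, SE 0.26). Camera gave adjusted p = 2.44e-09, and adjusted p = 0.332 with an estimated correlation. Of 11 heat shock genes 7 fell (8 adjusted over the list alone), among them HSP70 (log2 -6.53) and HSP90.1 (-5.07), with camera adjusted p = 0.00874 and adjusted p = 0.386 with an estimated correlation. Of 8 senescence and dark-induced genes 7 fell (8 adjusted over the list alone), among them DIN10 (log2 -3.98) and NYC1, a chlorophyll b reductase (-0.84), with camera adjusted p = 0.00748 and adjusted p = 0.245 with an estimated correlation. Of 6 brassinosteroid genes 5 fell (5 adjusted over the list alone), among them the synthesis enzymes CPD (log2 -1.40) and ROT3 (-2.69), with camera adjusted p = 0.00874 and adjusted p = 0.332 with an estimated correlation. Of 23 cell cycle and DNA replication genes 7 rose (7 adjusted over the list alone), among them MCM3, a helicase subunit (log2 0.76), and PCNA1, a replication clamp (0.88), with camera adjusted p = 0.00874 and adjusted p = 0.594 with an estimated correlation. Of 20 cell wall expansion genes 9 rose and 3 fell (9 and 3 adjusted over the list alone), with EXPA6 at log2 0.61 and XTH24 at -2.48, camera adjusted p = 0.0478 and adjusted p = 0.38 with an estimated correlation. The camera call of this list ended without Col-0 22 °C replicates 1 or 3 (0.0629, 0.0764) or Col-0 12 °C replicates 1 or 3 (0.0655, 0.0537).

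The remaining lists did not pass camera in Col-0. Of 11 flowering repressors 1 rose and 4 fell (1 and 4 adjusted over the list alone, camera adjusted p = 0.458). FLC, the repressor that vernalization silences, fell 5.41-fold (log2 -2.44, SE 0.23), and its span lies 100% under an antisense gene, and both held the same counts in all 12 libraries. MAF3, a relative of FLC, rose (log2 0.88), and TEM1 fell (-1.28). Of 9 flowering promoters 2 rose and 1 fell (2 and 1 adjusted over the list alone, camera adjusted p = 0.79), with AGL19 at log2 1.92 and SOC1, a floral integrator, at -0.68, while the list's median was 0.08 and its mean -0.01. Of 13 Polycomb and VIN3 family genes 5 rose and 1 fell (5 and 1 adjusted over the list alone, 0.14), among them CLF, a histone methyltransferase (log2 0.77). Of 8 DELLA proteins and gibberellin receptors 2 rose and 5 fell (2 and 5 adjusted over the list alone, 0.0943), among them the receptors GID1A (log2 -1.16) and GID1B (-1.72), and of 9 gibberellin metabolism genes 1 fell (0 adjusted over the list alone, 0.799). Of 18 circadian clock genes 9 rose and 4 fell (9 and 5 adjusted over the list alone, 0.145), among them LHY (log2 2.98) and PRR5 (1.23). Of 17 flavonoid and anthocyanin genes 6 rose and 3 fell (6 and 3 adjusted over the list alone, 0.199), among them TT4, the chalcone synthase (log2 1.93), and the repressor MYBL2 (-1.09). Of 24 nuclear photosynthesis genes 5 rose and 2 fell (5 and 2 adjusted over the list alone, 0.199), with RBCS1A at log2 0.64 and RBCS3B at -0.57. Of 12 sugar, starch and proline genes 2 rose and 5 fell (3 and 5 adjusted over the list alone, 0.471), with SUS1, a sucrose synthase, at log2 1.43 and PRODH1, a proline dehydrogenase, at -2.16.

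Of 9 abscisic acid response genes, 1 rose and 4 fell in Col-0 at 12 °C (1 and 6 adjusted over the list alone, camera adjusted p = 0.0943), among them RD22 (log2 -1.91). Of 18 salicylic acid defence genes 3 rose and 3 fell (2 and 3 adjusted over the list alone, 0.785), with PR5 at log2 -1.72 and EDS1 at 0.54, which was not called without both chloroplast-rich libraries (0.0894). Of 18 PIF and auxin growth genes 2 rose and 5 fell (3 and 5 adjusted over the list alone, 0.496), with IAA29 at log2 1.72, not called without Col-0 22 °C replicate 1 (0.0556) or without both chloroplast-rich libraries (0.206), and HFR1 at -3.43. Of 6 cell cycle inhibitors 3 fell (3 adjusted over the list alone, 0.0943), among them SMR1 (log2 -0.41, SE 0.08). Floral and meristem identity genes had 0 of 5 called (0 adjusted over the list alone, 0.198). Of the tissue markers, 1 of 2 seed and embryo markers fell (1 adjusted over the list alone, 0.74) and both tested root markers rose, 2 of 2 (2 adjusted over the list alone, 0.192).

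In vil1-1, rosettes at 12 °C also held more ELIP2 (72.9-fold, log2 6.19, SE 0.26, n = 3, adjusted p = 5.39e-08), ELIP1 (18.5-fold, log2 4.21, SE 0.18) and GolS3 (11-fold, log2 3.46, SE 0.20) than at 22 °C. VIN3 rose 45-fold, from 0.362 ± 0.146 to 16.5 ± 6.25 CPM (log2 5.49, SE 0.35, adjusted p = 1.16e-07). WRKY42, a transcription factor, rose 14.3-fold (log2 3.83, SE 0.29), and MPC, a gene for a poly(A)-binding protein domain, rose 12.9-fold (log2 3.68, SE 0.35). The falls included VSP1 (log2 -10.08, SE 0.62), VSP2 (-9.14, SE 0.76) and BAM5 (-8.61, SE 0.53). JRG21, a jasmonate-regulated dioxygenase, and TPS04, a terpene synthase, had 0 counts at 12 °C, at least 715-fold and at least 265-fold lower, and NATA1 was 1080-fold lower with a counting interval from 370 to 5250. AGL64, a MADS-box gene, passed at log2 5.23 (SE 1.81, adjusted p = 0.0487). It lost its call without any 1 of the 6 libraries, from 0.0625 without vil1-1 22 °C replicate 3 to 0.138 without vil1-1 22 °C replicate 1.

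The edgeR test called 8956 genes in vil1-1, 4235 higher and 4721 lower at 12 °C. At a fold of 2 or more, 660 were higher and 1749 lower. Tested against a fold of 1.5, 2139 genes were called and 29.5% of them were higher, compared with 47.3% in the test against no change. The ratio of 5′ UTR to 3′ UTR counts did not overlap between these groups, from 0.97 to 0.982 at 12 °C and from 0.83 to 0.858 at 22 °C. Its part in these calls was not tested.

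CBF1 rose in vil1-1 at 12 °C (log2 1.53, SE 0.27, adjusted p = 0.000443), as did CBF3 (0.61, SE 0.14, adjusted p = 0.00389) and CBF2 (0.55, SE 0.20, adjusted p = 0.0386), so 3 of 4 members of that list were called (3 adjusted over the list alone, camera adjusted p = 0.108). The CBF2 call ended without any 1 of vil1-1 22 °C replicates 1, 2 and 3 (0.0626, 0.0549, 0.14) or vil1-1 12 °C replicates 1 and 2 (0.157, 0.051). Of 19 COR genes 15 rose and 1 fell (15 and 1 adjusted over the list alone), among them COR47, a dehydrin (log2 1.18, SE 0.15), and COR15B (0.94, SE 0.12), with ZAT10, a zinc finger repressor, at -3.35. Camera gave adjusted p = 1.06e-05, and adjusted p = 0.485 with an estimated correlation. Jasmonate genes fell, 16 of 16 (16 adjusted over the list alone), with LOX2 at log2 -3.22, camera adjusted p = 1.4e-10 and adjusted p = 0.289 with an estimated correlation. Of 11 heat shock genes 9 fell (9 adjusted over the list alone), with camera adjusted p = 0.00596 and adjusted p = 0.471 with an estimated correlation. Of 8 senescence and dark-induced genes 6 fell (7 adjusted over the list alone), with camera adjusted p = 0.00645 and adjusted p = 0.289 with an estimated correlation. Of 24 nuclear photosynthesis genes 14 rose and 1 fell (16 and 1 adjusted over the list alone), with LHCB1.1 at log2 0.88, camera adjusted p = 3.42e-05 and adjusted p = 0.627 with an estimated correlation. Cell wall expansion genes had 9 of 20 higher and 2 lower (10 and 2 adjusted over the list alone), with EXPA11 at log2 2.71, camera adjusted p = 0.00645 and adjusted p = 0.289 with an estimated correlation.

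Of 18 circadian clock genes 7 rose and 3 fell in vil1-1 at 12 °C (10 and 3 adjusted over the list alone), with LHY at log2 3.43, camera adjusted p = 0.0405 and adjusted p = 0.485 with an estimated correlation. Their camera call ended without vil1-1 22 °C replicate 1 (0.0587) or vil1-1 12 °C replicate 1 (0.149). Of 8 DELLA proteins and gibberellin receptors 1 rose and 5 fell (1 and 5 adjusted over the list alone), with camera adjusted p = 0.0405, adjusted p = 0.289 with an estimated correlation, and 0.0584 without vil1-1 12 °C replicate 1. Of 6 brassinosteroid genes 1 rose and 4 fell (1 and 4 adjusted over the list alone), the rise being DWF4, a synthesis enzyme (log2 0.86), with camera adjusted p = 0.0405, adjusted p = 0.471 with an estimated correlation, and 0.0566 without vil1-1 12 °C replicate 3. Cell cycle and DNA replication genes had 2 of 23 higher and 1 lower (1 and 0 adjusted over the list alone, camera adjusted p = 0.599). Of 11 flowering repressors 2 rose and 4 fell (2 and 4 adjusted over the list alone, 0.478), with FLC at log2 -2.02. Of 9 flowering promoters 3 rose (3 adjusted over the list alone, 0.462), among them AGL19 (log2 3.12) and SOC1 (0.66, SE 0.18, adjusted p = 0.0125, and 0.0536 without vil1-1 22 °C replicate 1).

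The cold responses of the 2 genotypes, which share no library, had a Pearson r of 0.659 and a Spearman rho of 0.726 across 22504 genes, which are not independent replicates. Of the genes called, 6812 were called in both genotypes and 6803 of these moved in the same direction, while 1893.4 would be called in both in the same direction if the calls were independent. Among these, 3103 were higher in both and 3700 lower in both.

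**Figure D2:**
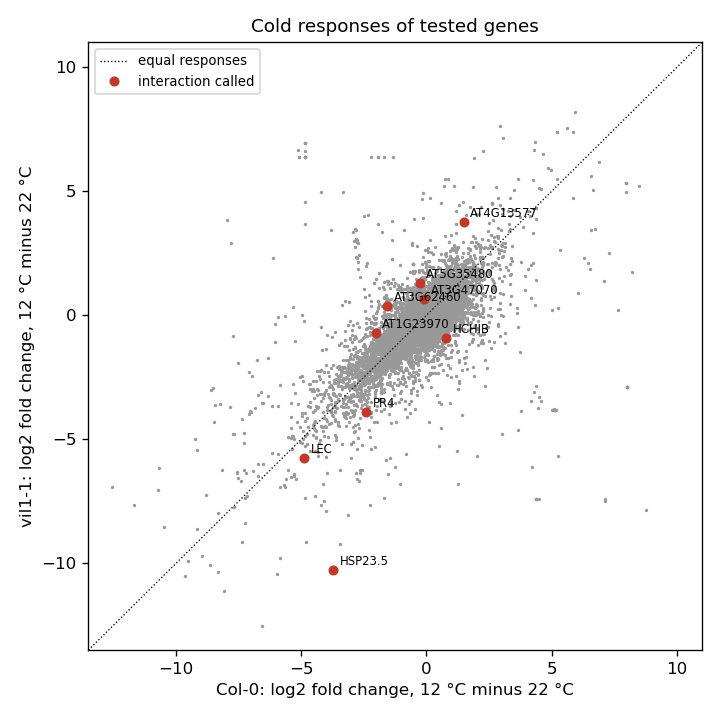
Log2 fold change at 12 °C relative to 22 °C in Col-0 (horizontal) and in vil1-1 (vertical); each grey point is 1 of 22504 tested genes, the dotted line marks equal responses, and red points are the 9 genes called in the interaction. HSP23.5, with 0 counts in vil1-1 at 12 °C, lies farthest below the line among the red points.

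At 22 °C, vil1-1 rosettes held more transcript of the flowering repressors FLC, MAF4 and MAF5 and less of the floral integrator SOC1 than Col-0. MAF3 (log2 -0.11, adjusted p = 0.787) and FLM (0.04, adjusted p = 0.932), relatives of FLC, did not pass. FLC was 3.69-fold higher, at 16.2 ± 3.09 against 4.38 ± 0.487 CPM (log2 1.88, SE 0.20, n = 3, adjusted p = 0.00041), and its counts hold both strands. MAF5 was 8.92-fold higher (log2 3.16, SE 0.41, adjusted p = 0.00242), MAF4 3.58-fold higher (log2 1.84, SE 0.35, adjusted p = 0.0277) and SOC1 2.94-fold lower (log2 -1.55, SE 0.18, adjusted p = 0.00156). PI4KG3, a phosphoinositide 4-kinase gene, stood at 31.6 ± 3.38 CPM in vil1-1 and 0.164 ± 0.0363 in Col-0 (log2 7.58, SE 0.23, adjusted p = 2.66e-10). QQS, a gene known for its effect on starch (log2 4.12, SE 0.47), PDF1.3, a defensin (3.80, SE 0.40), CAX3, a vacuolar cation exchanger (2.62, SE 0.45), and ATPMEPCRB, a pectin methylesterase (2.50, SE 0.25), also rose. CBR, an NADH-cytochrome b5 reductase, fell 5.95-fold (log2 -2.57, SE 0.11, adjusted p = 8.83e-09), and HAP8, named for a pollen defect (log2 -1.53, SE 0.11), SEP4, a MADS-box gene (-1.26, SE 0.17), and CYP76C6, a cytochrome P450 (-1.10, SE 0.23), fell too. CAX3 lost its call without Col-0 22 °C replicates 2 or 3 (0.057, 0.0577), MAF4 without these or vil1-1 22 °C replicates 1 or 2 (0.103, 0.0917, 0.089, 0.0859). CYP76C6 lost it without Col-0 22 °C replicates 1 or 3 or any 1 of vil1-1 22 °C replicates 1, 2 and 3 (0.164, 0.099, 0.193, 0.052, 0.148).

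The edgeR test called 201 genes between the genotypes at 22 °C, 134 higher and 67 lower in vil1-1. Fewer were called without Col-0 22 °C replicate 1 (101), vil1-1 22 °C replicate 1 (96) or vil1-1 22 °C replicate 3 (119), and without both chloroplast-rich Col-0 22 °C libraries 77 were called. DESeq2 called 515, and with the chloroplast share as a covariate 41 were called. The share of called genes that were higher in vil1-1 was 66.7%, and it was 49.4% of 235 genes without Col-0 22 °C replicate 3, 56.1% with the covariate and 58.6% with DESeq2. Without both chloroplast-rich libraries the calls of QQS (0.109), PDF1.3 (0.0522), MAF5 (0.075), MAF4 (0.146), CAX3 (0.0517), AGL19 (0.069) and CBF3 (0.148) ended.

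Flowering repressors had 3 of 11 members higher in vil1-1 at 22 °C (3 adjusted over the list alone), with camera adjusted p = 6.49e-05, and this call held with an estimated correlation (adjusted p = 0.04). Flowering promoters had 2 of 9 lower, SOC1 and AGL19, a MADS-box gene (log2 -1.61, SE 0.28, adjusted p = 0.0121), and 3 lower adjusted over the list alone. Camera gave adjusted p = 0.039 for these promoters, and adjusted p = 0.347 with an estimated correlation. AGL19 lost its call without vil1-1 22 °C replicates 2 or 3 (0.0584, 0.072), and the promoter list without Col-0 22 °C replicates 1 or 3 or vil1-1 22 °C replicates 1 or 3 (0.0745, 0.144, 0.174, 0.0516). Of the Polycomb and VIN3 family 2 of 13 fell, VIL1 and EMF1 (log2 -0.69), and 2 adjusted over the list alone (camera adjusted p = 0.0981). CBF3 was 1.77-fold higher in vil1-1, at 29.4 ± 3.25 against 16.6 ± 2.85 CPM (log2 0.82, SE 0.14, adjusted p = 0.0162). CBF1 (log2 0.66, SE 0.28, adjusted p = 0.419) and CBF2 (0.58, SE 0.20, adjusted p = 0.295) did not pass. The CBF list thus had 1 of 4 members called and 3 adjusted over the list alone, with camera adjusted p = 0.0044 and adjusted p = 0.251 with an estimated correlation. The CBF3 call ended without vil1-1 22 °C replicates 1 or 2 (0.0828, 0.0646), and the list's call without Col-0 22 °C replicate 3 (0.0618).

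Among COR genes, 1 of 19 was higher in vil1-1 at 22 °C, COR15B (log2 0.88, SE 0.12, adjusted p = 0.00224), and 3 were adjusted over the list alone. Camera gave adjusted p = 6.49e-05 for the COR list, adjusted p = 0.745 with an estimated correlation, and 0.144 without Col-0 22 °C replicate 3. Jasmonate genes had 0 of 16 called (0 adjusted over the list alone), with camera adjusted p = 0.00758 upward and adjusted p = 0.745 with an estimated correlation. Nuclear photosynthesis genes had 0 of 24 called (0 adjusted over the list alone), with camera adjusted p = 0.0126 downward and adjusted p = 0.817 with an estimated correlation. Both these directions turned without Col-0 22 °C replicate 3 (0.889 for jasmonate, 0.917 for photosynthesis), the Col-0 22 °C library with the lowest chloroplast share, 0.3% against 2.29% and 3.31% in the other Col-0 22 °C libraries. Their calls also ended without vil1-1 22 °C replicate 1 (0.217 for jasmonate, 0.0841 for photosynthesis), and that of photosynthesis without vil1-1 22 °C replicate 3 (0.431). RD29B, an abscisic acid responsive gene, rose 7.47-fold (log2 2.90, SE 0.40), and BAM5 rose 4.06-fold (2.02, SE 0.36, adjusted p = 0.0425).

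At 12 °C, vil1-1 rosettes held more transcript of KIN1, VIN3, FLC, MAF4 and MAF5 than Col-0, while MAF3 did not pass (log2 -0.01, adjusted p = 0.976). KIN1, a cold-induced hydrophilic protein, was 5.05-fold higher, at 775 ± 148 against 153 ± 24.1 CPM (log2 2.34, SE 0.35, n = 3, adjusted p = 0.0161). VIN3 was 3.46-fold higher (log2 1.79, SE 0.27, adjusted p = 0.00602), FLC 4.91-fold higher with both strands counted (log2 2.30, SE 0.23, adjusted p = 0.000183), MAF4 5.09-fold higher and MAF5 6.68-fold higher. PI4KG3 stood at 16.2 ± 1.46 against 0.0424 ± 0.0414 CPM (log2 8.42, SE 0.28), and QQS (5.32, SE 0.53), MPC (2.02, SE 0.32) and CIPK25, a protein kinase (1.66, SE 0.17), also rose. CBR fell 6.25-fold (log2 -2.64, SE 0.11, adjusted p = 7.1e-09) and HAP8 2.01-fold (-1.01, SE 0.11). KIN1 lost its call without any 1 of Col-0 12 °C replicates 1, 2 and 3 or vil1-1 12 °C replicate 1 (0.0806, 0.0726, 0.0529, 0.0692). VIN3 lost it without Col-0 12 °C replicate 1 (0.0516), and MAF5 without Col-0 12 °C replicates 2 or 3 (0.0514, 0.0513).

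The edgeR test called 462 genes between the genotypes at 12 °C, 364 higher and 98 lower in vil1-1. The count was 100, 139 and 149 without Col-0 12 °C replicates 1, 2 and 3, and 175, 209 and 950 without vil1-1 12 °C replicates 1, 2 and 3. DESeq2 called 1384, and the test against a fold of 1.5 called 19. Fewer than 462 were also called with the replicate block, as given below. The adjustment runs over all genes tested, so a single gene's call lost where fewer genes were called need not be particular to that gene. The ratio of 5′ UTR to 3′ UTR counts did not overlap between these groups, from 0.97 to 0.982 in vil1-1 and from 0.821 to 0.894 in Col-0. Its part in the 462 calls was not tested.

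CBF2 was 1.91-fold higher in vil1-1 at 12 °C, at 8.1 ± 1.74 against 4.23 ± 0.389 CPM (log2 0.94, SE 0.20, adjusted p = 0.0309), and CBF3 1.57-fold higher, at 45 ± 6.66 against 28.6 ± 3.79 CPM (log2 0.65, SE 0.14, adjusted p = 0.0355). CBF1 stood at 6.29 ± 1.4 and 4.14 ± 0.513 CPM (log2 0.60, SE 0.26, adjusted p = 0.226). The list of CBF and CBF-like factors had 2 of 4 higher and 3 adjusted over the list alone, with camera adjusted p = 0.00373 and adjusted p = 0.205 with an estimated correlation. The calls of CBF2 and CBF3 each ended without any 1 of Col-0 12 °C replicates 1, 2 and 3 or vil1-1 12 °C replicates 1 and 2. The adjusted p then lay between 0.0585 and 0.13 for CBF2 and between 0.0514 and 0.148 for CBF3. The count of all genes called also fell below 462 without each of these libraries, so these losses need not be particular to the CBF genes.

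**Figure D3:**
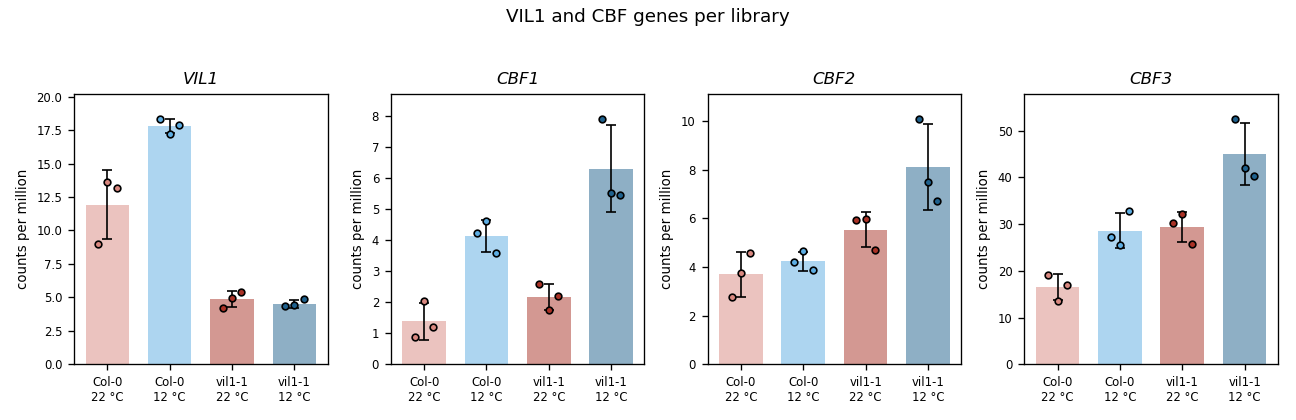
CPM of VIL1 and the 3 CBF genes in each library (points), with the mean (bars) and SD (error bars) of the 3 libraries of each group. Mean CBF3 is 16.6, 28.6, 29.4 and 45 CPM in the order Col-0 22 °C, Col-0 12 °C, vil1-1 22 °C and vil1-1 12 °C.

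Of 19 COR genes, 10 were higher in vil1-1 at 12 °C and 0 lower (16 adjusted over the list alone), with a median log2 of 0.73 and camera adjusted p = 1.34e-17, or adjusted p = 0.205 with an estimated correlation. COR15A (log2 0.90, SE 0.14), COR15B (0.77, SE 0.12), COR413-PM1 (0.55, SE 0.10) and LEA14 (0.74, SE 0.13) rose. Without vil1-1 12 °C replicate 1, the library apart on the second component, 3 COR genes were called and the median was 0.55. The ratio of 5′ UTR to 3′ UTR counts, from 0.97 to 0.982 in vil1-1 and from 0.821 to 0.894 in Col-0, differed between the groups along with these genes. The call of COR413-PM1 ended without any 1 of Col-0 12 °C replicates 1, 2 and 3 (0.0757, 0.0837, 0.061), and that of LEA14 without Col-0 12 °C replicates 1 or 2 or vil1-1 12 °C replicate 1 (0.0705, 0.0671, 0.0793).

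Of 23 cell cycle and DNA replication genes, 2 were lower in vil1-1 at 12 °C and 18 adjusted over the list alone, with a median log2 of -0.48 and camera adjusted p = 2.81e-12, or adjusted p = 0.205 with an estimated correlation. MCM2 (log2 -0.52, SE 0.12, adjusted p = 0.0407) and MCM3 (-0.47, SE 0.11, adjusted p = 0.0485), subunits of the replicative helicase, fell. The UTR count ratio differed between these groups here too, from 0.97 to 0.982 and from 0.821 to 0.894. Floral and meristem identity genes had 0 of 5 called and 1 lower adjusted over the list alone, KNAT6 (log2 -1.44, SE 0.41), with a median log2 of -1.44 and camera adjusted p = 0.0119 downward, or adjusted p = 0.205 with an estimated correlation and 0.145 without the low-count filter. Of the others, the meristem genes KNAT1 and STM had log2 -1.56 (SE 0.65) and -1.55 (SE 1.03), KNAT2 a mean of 0.333 CPM in vil1-1 and 0.669 CPM in Col-0, and SHP1, a carpel gene, log2 0.13 (SE 0.23). MCM2 and MCM3 lost their calls without any 1 of Col-0 12 °C replicates 1, 2 and 3 (0.163, 0.0836 and 0.124 for MCM2, 0.183, 0.0792 and 0.148 for MCM3) or vil1-1 12 °C replicates 1 and 2 (0.131 and 0.0886, 0.148 and 0.106). Flowering repressors had 4 of 11 higher, FLC, MAF4, MAF5 and FLM (log2 0.40, SE 0.08), and 4 adjusted over the list alone, with camera adjusted p = 0.000441 and adjusted p = 0.0844 with an estimated correlation. The FLM call ended without any 1 of the Col-0 12 °C libraries (0.0795, 0.111, 0.0849) or vil1-1 12 °C replicates 1 or 2 (0.081, 0.0544).

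Of 12 sugar, starch and proline genes 3 were higher in vil1-1 at 12 °C (6 adjusted over the list alone), GolS2, a galactinol synthase (log2 1.43, SE 0.31), SEX1, a glucan water dikinase (0.48, SE 0.10), and SPS1F, a sucrose phosphate synthase (0.28, SE 0.07). For this list camera gave adjusted p = 7.24e-05, and adjusted p = 0.205 with an estimated correlation. These calls each ended without any 1 of the Col-0 12 °C libraries or vil1-1 12 °C replicates 1 or 2, with adjusted p up to 0.153 for GolS2, 0.149 for SEX1 and 0.176 for SPS1F. Of 9 abscisic acid response genes 1 rose, RD29B (log2 3.38, SE 0.42, adjusted p = 0.00136), and 2 adjusted over the list alone, with camera adjusted p = 0.00285 and adjusted p = 0.205 with an estimated correlation. Of 6 brassinosteroid genes 1 rose, ROT3 (log2 1.23, SE 0.20), and 4 adjusted over the list alone, with camera adjusted p = 0.0119 and adjusted p = 0.205 with an estimated correlation. PIF and auxin growth genes had 0 of 18 called and 1 adjusted over the list alone, with camera adjusted p = 0.000495 upward and adjusted p = 0.205 with an estimated correlation. Nuclear photosynthesis genes had 0 of 24 called (0 adjusted over the list alone), with camera adjusted p = 3.12e-05 upward and adjusted p = 0.442 with an estimated correlation.

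**Figure D4:**
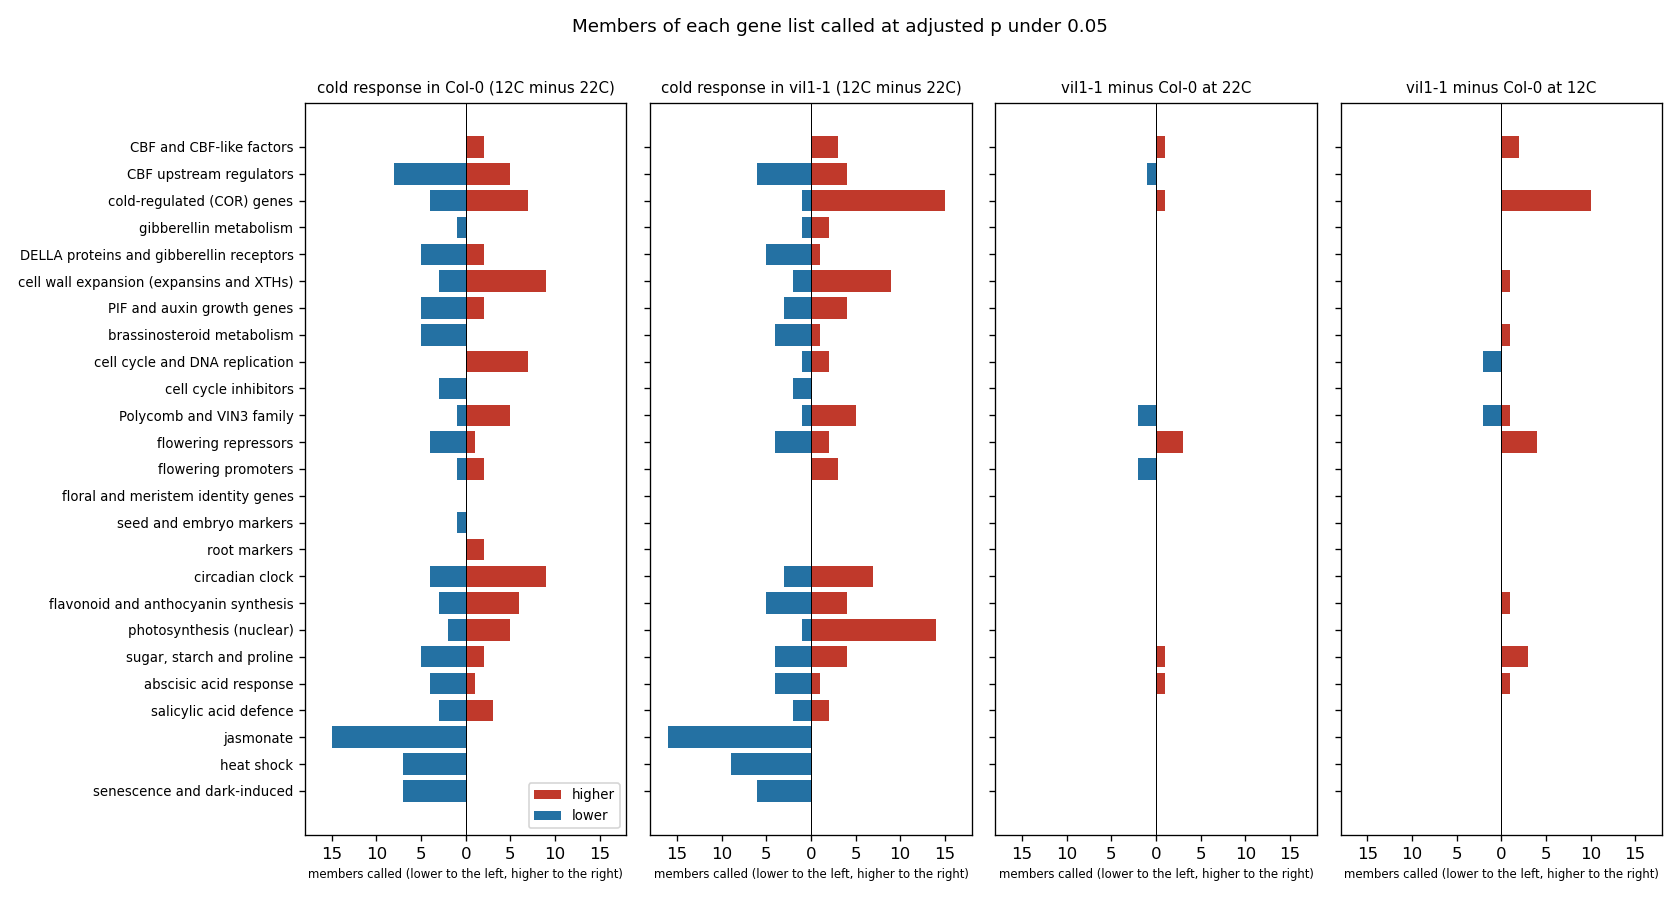
Number of members of each of the 25 lists called higher (red, to the right) or lower (blue, to the left) in the 4 single comparisons, by edgeR at adjusted p under 0.05. Jasmonate genes are lower at 12 °C in both genotypes (15 and 16 members), and 10 COR genes are higher in vil1-1 at 12 °C.

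Across temperatures, 71 genes differed between the genotypes at both 22 °C and 12 °C, and 70 of them in the same direction, 58 higher and 12 lower in vil1-1, while 2.5 would do so if the calls were independent. These 70 fall in 68 loci, since FLC and MES18 are each listed beside a gene on the other strand that overlaps them. The calls at both temperatures share the spread estimate of 1 fit, so they are not fully independent. The 70 genes included PI4KG3, QQS, FLC, MAF4, MAF5, CBF3, COR15B and RD29B as rises and CBR, HAP8, EMF1 and VIL1 as falls. At 12 °C the call of EMF1, a Polycomb-associated protein, ended without any 1 of Col-0 12 °C replicates 1, 2 and 3 or vil1-1 12 °C replicate 1 (0.0561, 0.0792, 0.0579, 0.0641). Across all 22504 genes, which are not independent replicates, the genotype effects had a Pearson r of 0.025 and a Spearman rho of 0.153. Leaving out 1 library at a time moved this r between -0.126 (without Col-0 12 °C replicate 3) and 0.105 (without Col-0 22 °C replicate 3), so its sign changed. Among genes at 10 CPM or more in 3 libraries it was 0.36.

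**Figure D5:**
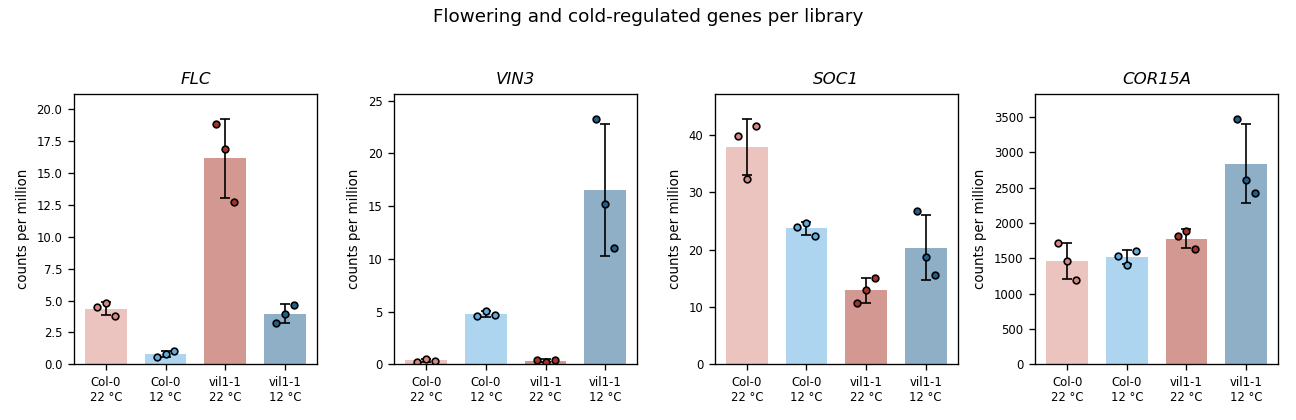
CPM of FLC, VIN3, SOC1 and COR15A in each library (points), with the mean (bars) and SD (error bars) of the 3 libraries of each group. Mean FLC is 16.2 CPM in vil1-1 at 22 °C against 4.38 in Col-0, and mean VIN3 is 16.5 CPM in vil1-1 at 12 °C against 4.78 in Col-0.

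The interaction test asked whether the response to 12 °C differed between the genotypes. PR4, a pathogenesis-related protein, fell in both genotypes and fell further in vil1-1 (log2 -3.89, SE 0.13) than in Col-0 (-2.41, SE 0.13), a difference of -1.47 (SE 0.17, adjusted p = 0.00974). Its call ended without vil1-1 12 °C replicate 2 (0.0574) and without both chloroplast-rich libraries (0.0724). HCHIB, a basic chitinase, rose in Col-0 (log2 0.79, SE 0.17) and fell in vil1-1 (-0.92, SE 0.17), a difference of -1.70 (SE 0.24, adjusted p = 0.0214). Its span lies 46.6% under a gene on the other strand, whose reads it may carry. HSP23.5, a small heat shock protein gene, went from 2.49 ± 0.596 to 0.186 ± 0.0313 CPM in Col-0 and from 3.47 ± 0.215 CPM to 0 counts in vil1-1, at least 149-fold lower (adjusted p of the difference = 0.0183). The calls of HCHIB and HSP23.5 ended without Col-0 22 °C replicate 1 (0.0535 for both) or Col-0 12 °C replicates 1 or 2 (0.071 and 0.0701 for both). They also ended without vil1-1 22 °C replicates 1 or 3 (0.0801 and 0.122 for HCHIB, 0.0773 and 0.0764 for HSP23.5), vil1-1 12 °C replicate 2 (0.0574 for both) or both chloroplast-rich libraries (0.0597 for both). That of HCHIB ended without vil1-1 22 °C replicate 2 (0.0656) or vil1-1 12 °C replicate 3 (0.055) as well. SOC1 fell in Col-0 and rose in vil1-1, and the difference of 1.34 (SE 0.25) did not pass (adjusted p = 0.129), nor did that of VIN3 (1.84, SE 0.49, adjusted p = 0.238). The CBF genes gave no called difference, with adjusted p = 0.97 for CBF1, 0.653 for CBF2 and 0.776 for CBF3.

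The edgeR test called 9 genes in the interaction. The signed difference in log2 response, vil1-1 minus Col-0, was positive for 5 and negative for 4. Of 22504 genes, 2601 had an unadjusted p under 0.05, where a share of 0.05 would pass by chance if no gene differed. The count of called genes was 1 without vil1-1 12 °C replicate 2, 2 without any 1 of Col-0 22 °C replicate 1, Col-0 12 °C replicates 1 and 2, and vil1-1 22 °C replicates 1 and 3, and 5 without vil1-1 22 °C replicate 2. It was 15 without Col-0 12 °C replicate 3 and 47 without Col-0 22 °C replicate 3, and DESeq2 called 224. Fewer than 9 were called with the replicate block and with the chloroplast covariate, as given below.

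Among the lists, COR genes had 0 of 19 called in the interaction and 8 adjusted over the list alone, with camera adjusted p = 2.81e-06 upward and adjusted p = 0.544 with an estimated correlation, and 0.242 without both chloroplast-rich Col-0 22 °C libraries. Cell cycle and DNA replication genes had 0 of 23 called and 1 adjusted over the list alone, with camera adjusted p = 1.34e-08 downward and adjusted p = 0.544 with an estimated correlation. Nuclear photosynthesis genes had 0 of 24 called (0 adjusted over the list alone), with camera adjusted p = 4.42e-08 upward and adjusted p = 0.544 with an estimated correlation.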

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

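The tests of 1 library that stands apart were chosen only after the COR and cell cycle results were seen, and the margins of spread used to judge all 4 tests of these lists were added after their values were known. A rule that the coverage test decides nothing where the ratio separates the groups was also added then and later withdrawn. With that rule coverage stayed open for the cell cycle list. Without it the median passed the bound by little more than its error, and no verdict on coverage is drawn from this below.

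The difference between the cold responses of vil1-1 and Col-0 passed the interaction test for 9 genes. PR4 (AT3G04720) differed by log2 -1.47, HCHIB (AT3G12500) by -1.70 and LEC (AT3G15356), a lectin-like protein, by -0.90. HSP23.5 (AT5G51440) had a fitted difference of -6.54, which depends on the prior count because vil1-1 held 0 counts at 12 °C. For 5 loci without a symbol the signed difference was positive, 2.30 for AT4G13577, 1.96 for AT3G62460, 1.57 for AT5G35480, 1.32 for AT1G23970 and 0.77 for AT3G47070. AT4G13577 rose more in vil1-1 (3.77) than in Col-0 (1.48), and AT1G23970 fell less in vil1-1 (-0.72) than in Col-0 (-2.03). AT3G62460 fell in Col-0 (-1.57) and did not pass in vil1-1, while AT5G35480 and AT3G47070 rose in vil1-1 (1.3 and 0.65) and did not pass in Col-0. Apart from AT4G13577 and PR4, each of the 9 calls ended without any 1 of Col-0 22 °C replicate 1, Col-0 12 °C replicates 1 and 2, vil1-1 22 °C replicates 1 and 3, and vil1-1 12 °C replicate 2, at adjusted p from 0.0535 to 0.174. By camera with the preset correlation, 6 lists differed between the cold responses, COR genes (adjusted p = 2.81e-06), cell cycle and DNA replication (1.34e-08), nuclear photosynthesis (4.42e-08), sugar, starch and proline (0.00235), PIF and auxin growth genes (0.0144) and brassinosteroid metabolism (0.0464), and for each adjusted p = 0.544 with an estimated correlation. Without both chloroplast-rich Col-0 22 °C libraries the COR list gave 0.242 and the sugar list 0.143. The PIF and auxin list gave 0.0769 without Col-0 22 °C replicate 3, 0.0592 and 0.0549 without Col-0 12 °C replicates 2 and 3, 0.0679 without vil1-1 22 °C replicate 3 and 0.119 without vil1-1 12 °C replicate 1. The brassinosteroid list gave 0.178 without Col-0 22 °C replicate 3, 0.121 and 0.0592 without Col-0 12 °C replicates 1 and 2, 0.0792 and 0.103 without vil1-1 22 °C replicates 2 and 3, and 0.119 and 0.1 without vil1-1 12 °C replicates 1 and 2.

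The COR genes were higher in vil1-1 at 12 °C with a median log2 of 0.73 (median SE 0.16, 18 of 19 members in this direction). Without vil1-1 12 °C replicate 1 the median was 0.55 (median SE 0.16; SE of the list's mean between libraries 0.18), 18 of 19 members were higher and camera with the preset correlation gave adjusted p = 1.29e-19, or adjusted p = 0.0804 with an estimated correlation. The list's mean between libraries was then 0.59 (SE 0.18), so a difference remained without that library. The median lay above 0.5 of its former value by little more than these errors. The called members went from 10 to 3 as the effect and the number of libraries fell. How much of the difference that library carries stays open. With the UTR count ratio as a covariate the median was 0.51 (median SE 0.20; SE between libraries 0.22), 18 of 19 members were higher, camera gave adjusted p = 1.96e-07, or adjusted p = 0.344 with an estimated correlation, and 1 member was called as the effect fell and its error grew. The median lay above 0.5 of its former value by less than its error, so coverage and genotype cannot be told apart for this list. The genotype itself stays open as a biological explanation.

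The cell cycle and DNA replication genes were lower in vil1-1 at 12 °C with a median log2 of -0.48 (median SE 0.22, 22 of 23 members in this direction). With the UTR count ratio as a covariate the median was -0.58 (median SE 0.31; SE between libraries 0.29), 23 of 23 members were lower and camera with the preset correlation gave adjusted p = 7.99e-09, or adjusted p = 0.344 with an estimated correlation, while 0 members were called as the standard error grew. The median lay beyond 0.5 of its former value by little more than its error, the outcome predicted if coverage were not the cause. However, the ratio does not overlap between these groups, and 83.6% of its variation within groups lies in Col-0 22 °C. For both lists the correction thus assumes the same slope at 12 °C, so it cannot decide whether coverage is the cause. Without vil1-1 12 °C replicate 1 the median was -0.32 (median SE 0.15), 22 of 23 members were lower, camera gave adjusted p = 7.3e-11, or adjusted p = 0.0804 with an estimated correlation, and 0 members were called as the effect fell. The list's mean between libraries was then -0.30 (SE 0.09), so a difference remained, but the median lay within its error of 0.5 of its former value, and how much of the difference that library carries stays open. The genotype stays open as an untested biological explanation, and so does a lower share of meristem tissue, since the floral and meristem identity genes had a median log2 of -1.44 in the same comparison (0 of 5 called, camera adjusted p = 0.0119, or adjusted p = 0.205 with an estimated correlation).

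Other splits of the libraries were tried for each count of called genes. For 3 libraries against 3 the 10 splits are too few for a share under 0.05, and 1 of the 10, the real split, gave as many genes in each single comparison. The real and highest other counts were 9483 and 0 for the cold response in Col-0, 8956 and 0 in vil1-1, 201 and 151 between genotypes at 22 °C, and 462 and 2 at 12 °C. The 151 genes came from the split that exchanges Col-0 22 °C replicate 2 and vil1-1 22 °C replicate 2. In the interaction, 1 of 50 relabellings of genotype within temperature, the real one, gave as many genes (9, highest other 5), a share of 0.02. Relabelling also mixes the genotypes, whose genes differ at each temperature, and so widens the spread within groups. It therefore cannot decide whether the 9 calls arose by chance.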

How the results depend on the processing

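Leaving out both chloroplast-rich Col-0 22 °C libraries and the chloroplast covariate were chosen after seeing the data. The cold response counts kept within 1.5 times their values in the other alternatives run, except that a test against a fold of 1.5 called 2367 in Col-0 and 2139 in vil1-1, by its construction, and 6272 were called in Col-0 without both chloroplast-rich libraries, with fewer samples. Between genotypes at 22 °C the count was 515 with DESeq2, 131 with the 10 CPM filter, 28 against a fold of 1.5, 81 at adjusted p under 0.01, 77 without the chloroplast-rich libraries and 41 with the chloroplast covariate. At 12 °C it was 1384 with DESeq2, 262 with the replicate block, 19 against a fold of 1.5 and 111 at adjusted p under 0.01. For the interaction it was 224 with DESeq2, 2 with the replicate block, 2 against a fold of 1.5, 2 at adjusted p under 0.01, 1 without the chloroplast-rich libraries and 3 with the covariate. Except for stricter thresholds and fewer samples or genes tested, the cause was not tested. Libraries with the same number did not pair, since their correlations ran from -0.189 to 0.173 and 4 of 12 libraries were closest to their own number. With the replicate block the other counts were 8881, 8419 and 143. Of the results for named genes and lists, 20 lost their call with the block and 256 kept their status. With the chloroplast covariate, 22 results for named genes lost their call, 215 kept their status and 2 changed sign. DESeq2's called genes at 12 °C were 68.3% higher in vil1-1, against 78.8% with edgeR, and in the interaction 72.3% against 55.6%. No scaling moved the median of all genes by over 0.1.

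Leaving out 1 library at a time gave 7927 to 8657 genes in the cold response of Col-0, 7542 to 8858 in vil1-1, 96 to 235 between genotypes at 22 °C, 100 to 950 at 12 °C and 1 to 47 in the interaction. VIL1 ranged from -1.47 to -1.19 at 22 °C and from -2.01 to -1.94 at 12 °C. The lists past camera ranged from 5 to 7 and 7 to 9 in the cold responses, 1 to 7 and 10 to 11 between genotypes at 22 °C and 12 °C, and 4 to 8 in the interaction. The correlation across genes ranged from 0.506 to 0.653 for the cold responses and from -0.126 to 0.105 for the genotype effects, and with the 10 CPM filter these were 0.918 and 0.36. The change of sign of the latter is not counted as a reversal, a rule set after it was seen, because 0.025 lies within its jackknife standard error of 0.204. With an estimated correlation 0, 0, 1, 0 and 0 lists passed in the 5 comparisons. Fry, which tests the members alone, passed 13 and 14 lists in the cold responses, 3 at 22 °C and 0 in the interaction. Between genotypes at 12 °C it passed flowering repressors (adjusted p = 0.00281), CBF factors and COR genes (0.0155 for both). Cell cycle, brassinosteroid (0.0328 for both), sugar (0.0333), floral and meristem (0.0413), gibberellin metabolism (0.0202) and Polycomb genes (0.0173) passed too. PIF and auxin, abscisic acid (0.0543 for both) and photosynthesis genes (0.214) did not pass fry there.

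The sign turned for CBF2 in the cold response of Col-0 (-0.12 without the chloroplast-rich libraries, -0.03 with the covariate), and for the interaction of CBF1, to 0.18 without Col-0 22 °C replicate 1, 0.03 without Col-0 22 °C replicate 3, 0.04 without Col-0 12 °C replicate 2, 0.08 without vil1-1 22 °C replicate 1, 0.04 and 0.05 without vil1-1 12 °C replicates 2 and 3, and 0 with the chloroplast covariate. It ranged down to -0.45 without Col-0 22 °C replicate 2, and neither was called. Without Col-0 22 °C replicate 3 the direction of the photosynthesis list (0.917) and of the jasmonate list (0.889) turned at 22 °C, while the lowest adjusted p with 1 library out was 2.16e-06 for photosynthesis without vil1-1 22 °C replicate 2 and 8.55e-08 for jasmonate without Col-0 22 °C replicate 2.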

Other observations

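The tests of gene families, and the bound used for the chromosome window, were chosen only after results were seen.

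Ribosomal protein genes rose at 12 °C in both genotypes. Of 112 nuclear genes with a symbol starting RPL, 103 rose and 0 fell in Col-0, and 104 rose and 0 fell in vil1-1, with median log2 changes of 0.69 and 0.66. RPL3B, a large subunit protein, rose by log2 1.90 (SE 0.11) in Col-0 and 2.44 (SE 0.11) in vil1-1. Of 94 RPS genes, 84 rose and 3 fell in Col-0, and 82 rose and 4 fell in vil1-1. Camera gave adjusted p = 6.18e-35 and 2.14e-34 for RPL genes, with adjusted p = 0.157 and adjusted p = 0.194 with an estimated correlation. For RPS genes it gave 3.65e-26 and 2.08e-25, with adjusted p = 0.188 and adjusted p = 0.263 with an estimated correlation. Between genotypes at 12 °C, RPL and RPS genes had median log2 differences of -0.1 and -0.12 in vil1-1, with 0 and 1 higher and 0 lower called. Camera gave adjusted p = 8.28e-06 downward for both, and adjusted p = 0.663 with an estimated correlation. These are 2 of 18 families defined by gene symbol and tried in all 5 comparisons. After a first run with 17 families had been seen, organelle genes and resistance genes named RPS were taken out and CIPK was separated from CML. Later, with results known, cyclophilins were taken out of CYP, peroxiredoxins out of the peroxidases, and 3 genes that are not aquaporins out of TIP.

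Families of specialised metabolism and transport held more falls than rises at 12 °C. Of 77 UGT genes, which encode glycosyltransferases, 45 fell and 5 rose in Col-0, and 40 fell and 3 rose in vil1-1. Of 135 CYP genes, which encode cytochrome P450 enzymes, 66 fell and 11 rose in Col-0, and 60 fell and 14 rose in vil1-1. Of 31 NPF transporter genes, 17 fell and 2 rose in Col-0, and 15 fell and 2 rose in vil1-1. These calls held with an estimated correlation, at adjusted p = 0.0458, 0.0269 and 0.0269 in Col-0 for UGT, CYP and NPF, and at adjusted p = 0.0421, 0.0346 and 0.0346 in vil1-1. Of 37 glutathione transferase (GST) genes, 20 fell and 4 rose in Col-0, and 19 fell and 2 rose in vil1-1. Of 16 TIP and PIP genes, 8 fell and 0 rose in Col-0, and 7 fell and 1 rose in vil1-1. With an estimated correlation camera did not call GST (adjusted p = 0.116 and 0.141) or TIP and PIP genes (0.12 and 0.265). Of 16 TIP and PIP aquaporin genes, 4 fell and 0 rose in vil1-1 relative to Col-0 at 22 °C, with camera adjusted p = 6.22e-07 and adjusted p = 0.122 with an estimated correlation. At 12 °C 0 fell and 1 rose, with a median log2 of 0.01 and camera adjusted p = 0.442. In the interaction 0 of these 16 genes were called, with camera adjusted p = 3.87e-05 upward and adjusted p = 0.262 with an estimated correlation. The families were tested in the main fit only, with no library left out and no chloroplast covariate.

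A hypothesis was that UGT genes and GST genes, which encode glutathione transferases, move upward as sets in vil1-1 at 12 °C. The larger camera adjusted p of these families was 0.257 with the preset correlation, that of UGT genes, while GST genes gave 0.0472, and 0.663 with an estimated correlation. The hypothesis was therefore not borne out for both families.

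Another hypothesis was that a chromosome segment may differ between the lines apart from VIL1, since PI4KG3 and CBR, which had the smallest p between the genotypes at each temperature, lie within 3 Mb of each other on chromosome 5. The 70 genes that differed in the same direction at both temperatures fall in 68 loci, and 8 of these lie in the fullest window of 3 Mb, from 5864182 to 8743880 on chromosome 5 (TAIR10), PI4KG3 and CBR, which prompted the test, among them. In 10000 random draws of as many loci the fullest window held a median of 6, and the permutation p was 0.137, so such a segment cannot be told apart from a chance cluster.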
